A study of Mus musculus with 16 samples.

How the data were processed

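Hypothalamic RNA of male mice was profiled on Illumina mouse bead arrays, with 16 arrays in 4 groups of 4. Per the labels' protocols, total RNA was extracted with DNase I treatment, its quality was checked on a Bioanalyser, and it was amplified to biotinylated cRNA. Groups and replicate numbers were taken from the sample titles, which give the genotype (AgRP+/- or AgRP-/-) and the feeding state, and the labels call the strain background mixed. The labels do not say whether each array holds RNA of a separate animal, so p-values measure the spread between these samples, which may be technical.

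The deposited table holds log2 intensities of 25697 probes, with 1 column per array. Per the submitters' processing notes limma was used, with neither its version nor its role stated, and the background correction and normalization method are not given in the sources used here. The deposited log2 values ran from 4.21 to 14.7. Sorted columns differed by at most 0.0345 and column medians by at most 0.00855, so the distributions of the arrays had been made nearly equal before deposit. Because of this, a change shared by most transcripts could not be measured. Detection p-values and bead counts were not used here, so a value near the low end of the scale could not be separated from background, and the number of arrays limits the precision. Slides and scan batches were not given in the sources used here.

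Probes were named from the platform annotation of the array, which can be old. It gave 1 gene symbol for 23978 probes, several for 0 and none for 1719. Through their gene identifiers 23962 probes matched a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table served only for names and for windows of 5, 10 and 20 megabases around Agrp, since the build behind the array was not given. No probe was named Agrp (0 probes), so the planned check of the deleted gene by name and the alternatives meant for it could not be run.

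Values were used as deposited. A probe was kept when its value exceeded the median of all values, 5.125, in at least 4 of the 16 arrays. This kept 13662 probes (53.2%), of which 12876 had a symbol, for 9530 genes. A gene with several kept probes was represented by the probe with the highest mean over the 16 arrays. A linear model with 1 coefficient per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, an intensity trend and 12 residual degrees of freedom. It gave 7 contrasts: fasting in each genotype, genotype in each feeding state, their interaction, and both averages. P-values were adjusted by the Benjamini-Hochberg method over the kept probes, and a probe was called at an adjusted p under 0.05. Changes are differences of log2 intensities, with the moderated standard error (SE) of the limma fit. Fisher's exact test, two-sided, was used for genes near Agrp, and an exact two-sided permutation test of 4 against 4 arrays, which can give no p below 0.0286, for the single probe that separated the genotypes.

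A total of 35 lists were fixed before the data were examined, 20 of them gene lists and 15 of them markers of cell types or regions, and so were the contrasts, the filter and the rule for named genes. The 33 lists with at least 5 kept genes were tested with camera at a preset correlation of 0.01 and adjusted over 231 tests, then again with an estimated correlation and with fry, which tests whether the genes of a list move on balance in a single direction. Members of each list were also adjusted over the list alone. The rule named, per contrast, Agrp, Npy, Pomc and Cartpt; the 10 largest rises and the 10 largest falls among called genes; the 4 members with the smallest p of each list that passed camera or held a called member; and every called gene of the interaction and of a genotype contrast with 10 or fewer calls. Named outside the rule, after their values were seen, were Actb, Gh, Prl, Th, Chrnb3, Lmx1a and En2, the other midbrain transcripts, the probe without a symbol, and single contrasts of genes that the rule named in another contrast.

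Alternatives chosen with the contrasts were no filter, a stricter filter at the 75th percentile of all values (7.733, which kept 6719 probes), quantile normalization once more, median centring, no intensity trend, array weights, a fit to the compared groups alone, the replicate number as a block, 1 probe per gene, and leaving out each array in turn. Chosen after seeing the data were the difference between the dimmest and the brightest kept Actb probe as a covariate, the mean of Slc6a3, Chrna6 and Th as a covariate, and a fit without 2 arrays that carried pituitary transcripts. The model was tested on simulated data with 13662 probes, of which 67 were shifted by 0.5, 67 by 1 and 66 by 2 on the log2 scale. It recovered 49.3%, 98.5% and 100% of them for fasting in AgRP+/- with 8 false calls, 41.8%, 95.5% and 100% for fasting in AgRP-/- with 11 false calls, and 74.6%, 100% and 100% for fasting averaged over genotypes with 8 false calls. Simulated values were drawn independently for each probe and array from normal distributions with the moderated SDs of the fit. Variation shared between probes was left out, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.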

Results

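Gene expression was measured in the hypothalamus of male mice with either 1 or no intact copy of the gene for agouti-related peptide, a peptide of arcuate neurons that promotes feeding. Heterozygous (AgRP+/-) and knockout (AgRP-/-) mice were fed ad libitum or fasted for 30 h, with 4 arrays in each of the 4 groups. Pairs of arrays correlated between 0.9805 and 0.9928, and the first principal component held 16.5% of the variance. The design addresses how the hypothalamic transcriptome responds to fasting and whether that response depends on the peptide.

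No probe was named Agrp, so the deleted gene was not read by name. A single probe without a symbol, ILMN_2703427, separated the genotypes in both feeding states. It read 8.36 ± 0.70 (SD, n = 4) in fed and 10.36 ± 0.59 (SD, n = 4) in fasted AgRP+/- mice. In AgRP-/- mice it read 4.50 ± 0.047 and 4.50 ± 0.085 (SD, n = 4), near the lower quartile of 4.49 on these arrays, where signal could not be separated from background. The measured genotype differences of -3.85 in fed and -5.86 in fasted mice are therefore bounds, since a floor in AgRP-/- mice limits their size (limma adjusted p = 1.49e-07 and 7.14e-11), and the exact two-sided permutation p was 0.0286 in both, the smallest that 4 against 4 arrays can give. The same probe rose with fasting in AgRP+/- mice by 2.01 (SE 0.27, limma adjusted p = 0.000695) and read -0.0061 in AgRP-/- mice, where a change could not be read at that floor, and the interaction of -2.01 (adjusted p = 0.577) is set by the same floor. Because the probe has no symbol in the annotation used here, it does not check the genotype labels by gene.

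In fasted AgRP+/- mice 8 of 25 kept glucocorticoid responsive genes were called higher and 0 lower (camera adjusted p = 6.64e-15; adjusted p = 0.0942 with an estimated correlation). Plin4, a coat protein of lipid droplets, rose by 3.48 on the log2 scale (SE 0.27, limma adjusted p = 1.02e-06), or 11.1-fold. Mfsd2a, a lipid transporter of brain endothelium, rose by 0.90, while Slc38a5, an amino acid transporter, decreased by 1.09 and the chemokine gene Cxcl12 decreased by 0.78. Npy, the feeding peptide made by the same arcuate neurons as agouti-related peptide, rose by 0.87 (SE 0.20, adjusted p = 0.0472). Cdkn1a, a cell cycle inhibitor, rose by 1.31 (adjusted p = 0.0185). Its call was lost without AgRP+/- fed replicate 1, 2 or 4 or AgRP+/- fasted replicate 1 or 2 (changes from 1.04 to 1.27, adjusted p from 0.0563 to 0.0868) and with these groups fitted alone (0.111). Sult1a1, a sulfotransferase, rose by 1.51 (adjusted p = 0.0418). Its call was lost without AgRP+/- fed replicate 1, 2 or 3 or AgRP+/- fasted replicate 1, 2 or 4 (changes from 1.20 to 1.63, adjusted p from 0.054 to 0.14), without the filter, without the trend, with these groups alone and with replicate numbers as a block (0.055, 0.0955, 0.111 and 0.0675). Gkn3 decreased by 1.07 (adjusted p = 0.0314). Its call was lost without AgRP+/- fed replicate 1, 2 or 4 or AgRP+/- fasted replicate 1, 2 or 4 (changes of -0.80 or larger in size, adjusted p of 0.0555 or more), without the filter, without the trend and with these groups alone (0.0625, 0.0647 and 0.111).

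A total of 103 probes were called with limma, 78 higher and 25 lower, for 87 named genes. Other large rises were those of Lrrc8a, a subunit of a volume-regulated anion channel (1.48), Itgad, an integrin chain (1.37), Hr, a corepressor regulated by thyroid hormone (1.22), Nkain1 (0.96) and Hsd17b11 (0.86). Other falls were those of Lhx8, a transcription factor of forebrain neurons (-1.02), Rnase1 (-0.74), Greb1 (-0.73), Hmgb2 (-0.70), Pkd2l1 (-0.69), Itm2a (-0.67) and Tst (-0.59). Dimmer probes disagreed for Lrrc8a (0.303, adjusted p = 0.408) and for Cxcl12 (-0.255 and -0.0894, adjusted p = 0.792 and 0.914).

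Of the 25 glucocorticoid responsive genes 14 were higher when adjusted over the list alone, with a list median of 0.34 (adjusted p = 0.0942 with an estimated correlation). The list median was 0.51 without AgRP+/- fed replicate 3. The mean of the list, relative to all arrays, was -0.025 in AgRP+/- fasted replicate 3, against 0.32 to 0.53 in the other fasted and -0.38 to -0.16 in the fed AgRP+/- arrays. Without that fasted array the list median was 0.41. Called members included Angptl4, a lipase inhibitor (0.81), and Fam107a (0.65). Targets of FoxO factors and insulin signalling had a median of 0.17 over 15 genes, with 0 called and 3 higher when adjusted over the list alone (camera adjusted p = 0.00283; adjusted p = 0.0942 with an estimated correlation). Among them the transcription factor gene Foxo1 read 0.39 and Pik3r1, a subunit of phosphoinositide 3-kinase, 0.32. Interferon response genes had a median of -0.26 over 16 genes, with 0 called and 2 lower when adjusted over the list alone (camera adjusted p = 0.00599; adjusted p = 0.715 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.070 over 70 genes with 0 called and 0 when adjusted over the list alone (camera adjusted p = 0.00362; adjusted p = 0.918 with an estimated correlation). Among 28 neuropeptide genes only Npy was called (1 higher and 0 lower, 2 and 2 when adjusted over the list alone). Gal read -0.52, Nts -0.78, Pomc -0.058 and Cartpt 0.12, with adjusted p of 0.106, 0.08, 0.943 and 0.697. Fgfr3 (0.58) was the called member of 12 astrocyte markers, and among 11 endothelial markers Pglyrp1 (0.85) rose and Itm2a fell.

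The count was 30 when these groups were fitted alone and 45 without the 2 arrays that carried pituitary transcripts, and with the dopamine transcripts and the Actb difference described with the averaged contrast as covariates it was 19 and 63. Calls lost with the former included Cdkn1a (1.13, SE 0.30, adjusted p = 0.151), Sult1a1 (1.15, SE 0.38, adjusted p = 0.263), Gkn3 (-0.85, SE 0.26, adjusted p = 0.222), Mfsd2a (0.77, SE 0.16, adjusted p = 0.0734) and Npy (0.97, SE 0.24, adjusted p = 0.131). Itgad, Hr, Nkain1, Hsd17b11, Pglyrp1, Angptl4, Fam107a, Fgfr3, Tst, Pkd2l1, Hmgb2, Greb1, Rnase1 and Lhx8 also lost theirs (adjusted p from 0.0579 to 0.161). With the latter lost calls included Cdkn1a (1.42, SE 0.32, adjusted p = 0.054) and Npy (1.04, SE 0.24, adjusted p = 0.0612). Nkain1, Hsd17b11, Angptl4, Fgfr3, Pkd2l1, Hmgb2, Rnase1 and Lhx8 also lost theirs with the latter (adjusted p from 0.0501 to 0.203). SEs of kept probes grew 1.19-fold with the former and 1.2-fold with the latter in the median. Without the 2 arrays lost calls included those of Cdkn1a (1.27, adjusted p = 0.0757), Sult1a1 (1.25, adjusted p = 0.123), Gkn3 (-0.99, adjusted p = 0.0955) and Npy (0.82, adjusted p = 0.145). The count was 41, 63 and 68 without AgRP+/- fed replicates 1, 2 and 4, and 49, 42 and 67 without fasted replicates 1, 2 and 4. Npy lost its call without any of these arrays or fasted replicate 3, at 0.0523 to 0.167 in adjusted p and changes of 0.72 to 1.08 over all left-out arrays, and without the filter, with the stricter filter, without the trend or with these groups alone (0.0625, 0.0515, 0.108 and 0.11). Calls were also lost for Angptl4, Fam107a, Fgfr3, Hmgb2, Hr, Hsd17b11, Itgad, Lhx8, Nkain1, Pglyrp1, Pkd2l1 and Rnase1 with at least 1 array left out, and Greb1 and Tst under another alternative.

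In AgRP-/- mice fasting also raised Plin4, by 3.28 (SE 0.27, limma adjusted p = 2.82e-06), or 9.7-fold. Itgad rose by 1.43, Lrrc8a by 1.26 and Mfsd2a by 0.92. Rbm3, an RNA-binding protein induced by cold, rose by 0.96 (adjusted p = 0.00325), while its dimmer probe read -0.469 (adjusted p = 0.339). Gkn3 decreased by 1.45, Rnase1 decreased by 0.99 and Cxcl12 decreased by 0.76. Egr1, a transcription factor induced by neuronal activity, decreased by 0.72. Sult1a1 rose by 1.84 and Cdkn1a by 1.39 (adjusted p = 0.0162 and 0.0162). The call was lost for Sult1a1 without AgRP-/- fed replicate 1, 2 or 4 or AgRP-/- fasted replicate 1 or 2 (changes from 1.65 to 1.82, adjusted p from 0.0523 to 0.0804), for Cdkn1a without AgRP-/- fed replicate 1 or AgRP-/- fasted replicate 2 or 4 (changes from 1.31 to 1.35, adjusted p from 0.052 to 0.0724), and for both without the trend (0.0551 and 0.0517). Egr4, a related factor, decreased by 0.88 (adjusted p = 0.0413). Its call was lost without AgRP-/- fed replicate 1, 2, 3 or 4 or AgRP-/- fasted replicate 1, 2 or 4 (changes from -0.93 to -0.78, adjusted p from 0.0656 to 0.148), without the filter and without the trend (0.0649 and 0.0729).

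A total of 53 probes were called with limma, 37 higher and 16 lower, for 45 named genes. Angptl4 (0.95), Pglyrp1 (0.79) and Rpl3l (0.77) rose, as did Psat1, an enzyme of serine synthesis (0.46). Dok3 (-0.70), Hoxc4 (-0.68), Tst (-0.62), Mafg (-0.56) and Trhr, the receptor for thyrotropin-releasing hormone (-0.56), fell. Npy read 0.85 (SE 0.20, adjusted p = 0.069), Pomc -0.17 (adjusted p = 0.774) and Cartpt -0.077 (adjusted p = 0.827).

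Of the 25 glucocorticoid responsive genes 6 were called higher and 0 lower, and 15 were higher when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 5.76e-13; adjusted p = 0.109 with an estimated correlation). Cholesterol synthesis genes had a median of -0.18, with 17 of 18 below 0, 0 called and 1 lower when adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.223 with an estimated correlation). The sterol enzyme genes Msmo1, Sqle and Dhcr7 read -0.32, -0.25 and -0.50. Genes of fatty acid oxidation and ketone use had a median of 0.068 over 21 genes, with 1 called, Angptl4, and 4 higher when adjusted over the list alone (camera adjusted p = 0.0398; adjusted p = 0.205 with an estimated correlation). FoxO and insulin signalling targets had a median of 0.14 with 0 of 15 called and 2 higher when adjusted over the list alone (camera adjusted p = 0.041; adjusted p = 0.223 with an estimated correlation). All 9 kept genes of inflammation and the acute phase lay above 0, with 0 called, 2 higher when adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.0364; adjusted p = 0.59 with an estimated correlation). Lrg1 read 1.11 and Serpina3n 0.57.

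The count was 29 without the intensity trend, 143 with array weights and 87 when these groups were fitted alone, and 1 and 83 with the dopamine transcripts and the Actb difference as covariates. With the former only Plin4 was called, and with the latter Egr4 lost its call at -0.89 (SE 0.22, adjusted p = 0.0864). Rpl3l, Hoxc4, Mafg and Dok3 also lost theirs with the Actb difference (adjusted p from 0.0694 to 0.129). With the dopamine transcripts lost calls included Mfsd2a (0.72, SE 0.19, adjusted p = 0.288), Gkn3 (-1.13, SE 0.30, adjusted p = 0.288), Egr1 (-0.47, SE 0.14, adjusted p = 0.362), Cdkn1a (1.12, SE 0.35, adjusted p = 0.373), Sult1a1 (1.29, SE 0.44, adjusted p = 0.428) and Egr4 (-0.65, SE 0.25, adjusted p = 0.495), while SEs grew 1.38-fold in the median. The count was 30 without AgRP-/- fed replicate 4, and 35, 27 and 31 without fasted replicates 1, 2 and 3, and Npy was called without fasted replicate 1 (adjusted p = 0.0487). Dok3, Hoxc4, Mafg, Pglyrp1, Psat1, Rpl3l and Trhr lost their calls with at least 1 array left out.

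The fasting changes of the genotypes ran mostly in the same direction. Of 123 probes called in either genotype 121 had the same sign in the other, 28 were called higher and 5 lower in both, where independent lists would share 0.211 and 0.0293, and 0 were called in opposite directions. Across kept probes, which are not independent replicates, the fasting changes had a Pearson correlation of 0.498 and a Spearman correlation of 0.464. The interaction called 0 probes with limma, with 371 at an unadjusted p under 0.05 where 683 would be expected by chance. Its SE is larger than that of fasting in a single genotype, at 0.382 against 0.27 for ILMN_2703427. The simulated data held no interaction, so the power to call one was not measured. The 0 calls therefore do not show that the fasting response is the same in both genotypes. The interaction was -0.020 for Npy and -0.62 for Egr1, which were each called in a single genotype (adjusted p = 0.999 and 0.999), and -0.11 for Pomc and -0.20 for Cartpt. Without AgRP+/- fed replicate 3 the interaction called 1 probe.

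**Figure D1:**
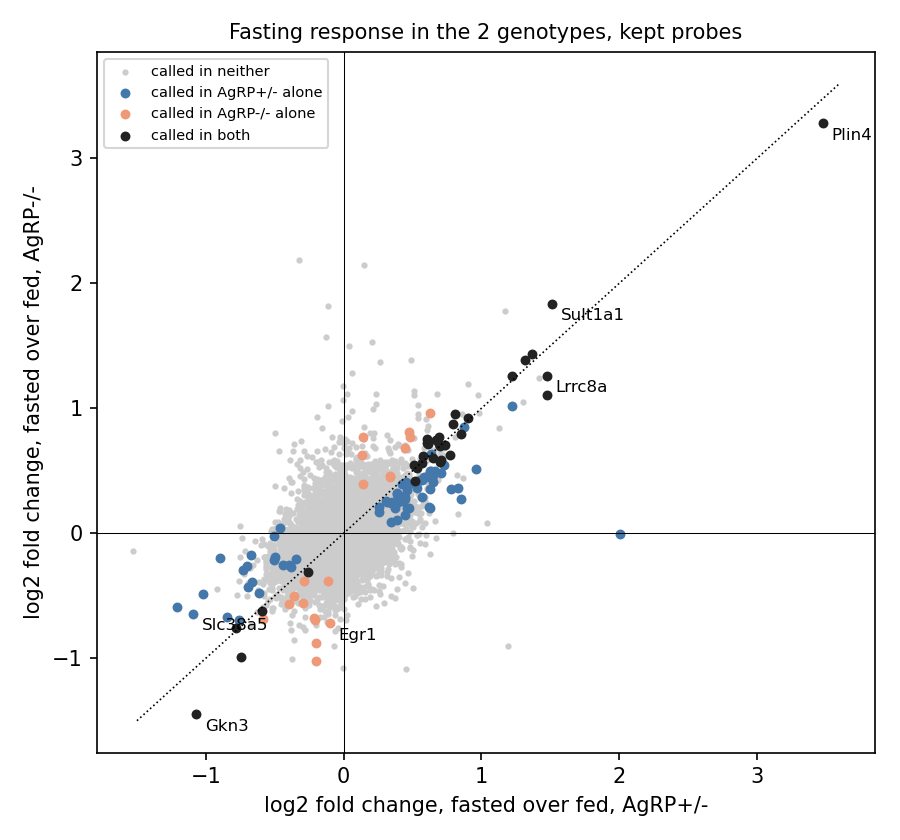
Log2 fold change of fasted over fed mice in AgRP+/- (x axis) against AgRP-/- (y axis), with 1 point per kept probe, coloured by the genotype in which the probe was called. Of the 123 called probes 121 have the same sign on both axes, and Plin4 stands apart at 3.48 and 3.28.

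Averaged over genotypes, 12 of 25 glucocorticoid responsive genes were called higher after fasting and 0 lower (camera adjusted p = 3.43e-15; adjusted p = 0.0942 with an estimated correlation). Npy rose by 0.86 (SE 0.14, limma adjusted p = 0.0016), while the peptide genes Gal and Nts decreased by 0.42 and decreased by 0.63, and the immediate early genes Egr1 and Fos decreased by 0.41 and decreased by 0.61. The fall of Egr1 was called in AgRP-/- mice (-0.72) and not in AgRP+/- mice, whose fasted arrays read 11.2 to 11.8 against 11.4 to 11.9 in fed. Oxt decreased by 0.39 and Egr4 decreased by 0.54 (adjusted p = 0.0252 and 0.0271). The call was lost for Oxt without AgRP+/- fed replicate 3, AgRP+/- fasted replicate 2 or AgRP-/- fasted replicate 1 (changes from -0.35 to -0.33, adjusted p from 0.051 to 0.0565) and without the trend. For Egr4 it was lost without AgRP+/- fed replicate 3 or 4, AgRP-/- fed replicate 2 or 3, AgRP+/- fasted replicate 2 or AgRP-/- fasted replicate 1 or 2 (changes from -0.52 to -0.48, adjusted p from 0.0504 to 0.0651). With the dopamine transcripts given below as a covariate the calls were lost for Egr1 (-0.20, SE 0.11, adjusted p = 0.465), Oxt (-0.081, SE 0.10, adjusted p = 0.795), Egr4 (-0.35, SE 0.19, adjusted p = 0.456) and Nts (-0.44, SE 0.20, adjusted p = 0.366), and, at changes of similar or larger size, for Gal (-0.40, SE 0.15, adjusted p = 0.281), Fos (-0.65, SE 0.21, adjusted p = 0.202) and Npy (0.98, SE 0.21, adjusted p = 0.0584). With the Actb difference they were lost for Fos (-0.29, SE 0.15, adjusted p = 0.39), and, at changes of similar or larger size, for Egr1 (-0.41, SE 0.12, adjusted p = 0.0816), Oxt (-0.39, SE 0.13, adjusted p = 0.143), Egr4 (-0.55, SE 0.18, adjusted p = 0.137) and Gal (-0.51, SE 0.13, adjusted p = 0.0613). Sgk1, a kinase induced by glucocorticoids, rose by 0.97, and Pdk4, which restrains glucose oxidation, by 0.67. With the Actb difference the calls were lost for Sgk1 (0.84, SE 0.25, adjusted p = 0.103) and Pdk4 (0.73, SE 0.18, adjusted p = 0.0504). Gkn3 decreased by 1.26, Slc38a5 decreased by 0.87 and Lama4, a laminin chain of vessel walls, decreased by 0.59. With the dopamine transcripts as a covariate the calls were lost for Pdk4 (0.71, SE 0.20, adjusted p = 0.136), Gkn3 (-0.99, SE 0.23, adjusted p = 0.072) and Lama4 (-0.77, SE 0.19, adjusted p = 0.0817).

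A total of 572 probes were called with limma, 305 higher and 267 lower, for 493 named genes, with a median size of 0.357 on the log2 scale. Of the 25 glucocorticoid responsive genes 17 were higher when adjusted over the list alone (median 0.39, adjusted p = 0.0942 with an estimated correlation). Among 15 FoxO and insulin signalling targets Txnip (0.57), Sesn1 (0.33), Foxo1 (0.32) and Pik3r1 (0.21) were called higher, and 6 when adjusted over the list alone (median 0.13, camera adjusted p = 0.00322; adjusted p = 0.0942 with an estimated correlation). Among 18 cholesterol synthesis genes Msmo1 (-0.24) and Nsdhl (-0.32) were called lower, and 4 when adjusted over the list alone (median -0.16, camera adjusted p = 0.00283; adjusted p = 0.297 with an estimated correlation). Among 16 interferon response genes Ifit3 (-0.50), Gbp3 (-0.49) and Gbp2 (-0.42) were called lower, and 3 when adjusted over the list alone (median -0.22, camera adjusted p = 0.0335; adjusted p = 0.83 with an estimated correlation). With the dopamine transcripts as a covariate Ifit3, Gbp3 and Gbp2 lost their calls at -0.26, -0.25 and -0.43 (limma adjusted p = 0.496, 0.506 and 0.243). With the Actb difference their calls were lost at -0.48, -0.53 and -0.33 (limma adjusted p = 0.128, 0.0875 and 0.228). Txnip, Sesn1, Foxo1, Pik3r1, Msmo1 and Nsdhl also lost their calls with the dopamine transcripts (limma adjusted p = 0.13, 0.0831, 0.101, 0.159, 0.407 and 0.231). With the Actb difference Sesn1 kept its call (adjusted p = 0.0461). Txnip, Foxo1, Pik3r1, Msmo1 and Nsdhl lost theirs at 0.59, 0.24, 0.27, -0.11 and -0.29 (adjusted p = 0.102, 0.267, 0.0921, 0.525 and 0.248). Of 70 oxidative phosphorylation genes 0 were called, 0 when adjusted over the list alone, and 53 lay below 0 (median -0.054, camera adjusted p = 0.00362; adjusted p = 0.918 with an estimated correlation).

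Lists that did not pass camera still held called members. Among 28 neuropeptide genes 1 was called higher and 3 lower (3 and 5 when adjusted over the list alone; camera adjusted p = 0.718). Among 21 genes of fatty acid oxidation and ketone use 4 were called higher (4 when adjusted over the list alone; camera adjusted p = 0.116), among them Pdk4, Acat1 (0.46) and Ppargc1a (0.34). Of the called members Pdk4 and Angptl4 are also on the glucocorticoid list. Among 20 immediate early genes Egr1 (-0.41), Fos (-0.61) and Egr4 (-0.54) fell (3 when adjusted over the list alone; camera adjusted p = 0.334). Among 17 clock genes Dbp (-0.31) and Ciart (-0.38) fell (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.449). Among 11 genes of the thyroid axis Hr (1.12) rose and Trhr (-0.48) and Slco1c1, a thyroid hormone transporter (-0.29), fell (1 and 3 when adjusted over the list alone; camera adjusted p = 0.607). Among 11 oligodendrocyte markers Mobp (0.50) rose and Ugt8a (-0.43) and Opalin (-0.55) fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.773). Acat1, Ppargc1a, Dbp, Ciart, Hr, Trhr, Slco1c1, Mobp, Ugt8a and Opalin lost their calls with the dopamine transcripts (limma adjusted p from 0.11 to 0.581). With the Actb difference Ciart, Hr and Trhr kept their calls (adjusted p = 0.0245, 0.000979 and 0.00811). The others lost theirs, with Acat1 at 0.23 and Slco1c1 at -0.14 (adjusted p = 0.518 and 0.544).

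Of 12 kept transcripts of midbrain dopamine neurons, listed after the called genes were seen, 5 were called higher after fasting and 7 were not called, with changes from 0.18 to 0.44 (limma adjusted p from 0.0597 to 0.56). Slc6a3, the dopamine transporter, rose by 1.48 (SE 0.38, limma adjusted p = 0.033), the nicotinic receptor genes Chrna6 and Chrnb3 by 1.05 and 0.72, Th, which makes the dopamine precursor, by 0.64, and the transcription factor gene Lmx1a by 0.58 (adjusted p = 0.00937, 0.00614, 0.0175 and 0.0232). Of 5 kept Actb probes the dimmest read 1.23 and 1.33 after fasting and the brightest 0.40, which were called, and the others -0.064 and -0.21. Pituitary transcripts stood out on 2 fed arrays, with Gh at 7.78 and Prl at 7.34 in AgRP+/- fed replicate 2 and at 6.14 and 5.17 in AgRP-/- fed replicate 1.

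With the dopamine transcripts as a covariate 33 probes were called and with the Actb difference 176, while the SEs of kept probes grew 1.5-fold and 1.33-fold in the median. The count was 301 without AgRP+/- fasted replicate 2, 380 without AgRP+/- fed replicate 4, 364 without AgRP-/- fed replicate 3 and 368 without AgRP-/- fasted replicate 1, and 40 of 64 called named genes kept their call whichever array was left out. Those that did not were Acat1, Atf5, Clic6, Ctsb, Cx3cr1, Dlx1, Egr4, Elovl5, Enpp6, Foxo1, Hspa8, Lamp1, Mobp, Msmo1, Nsdhl, Oxt, Pik3r1, Plac9a, Ppargc1a, Rpl3l, Rps2, Slc6a3, Slco1c1 and Sostdc1.

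**Figure D2:**
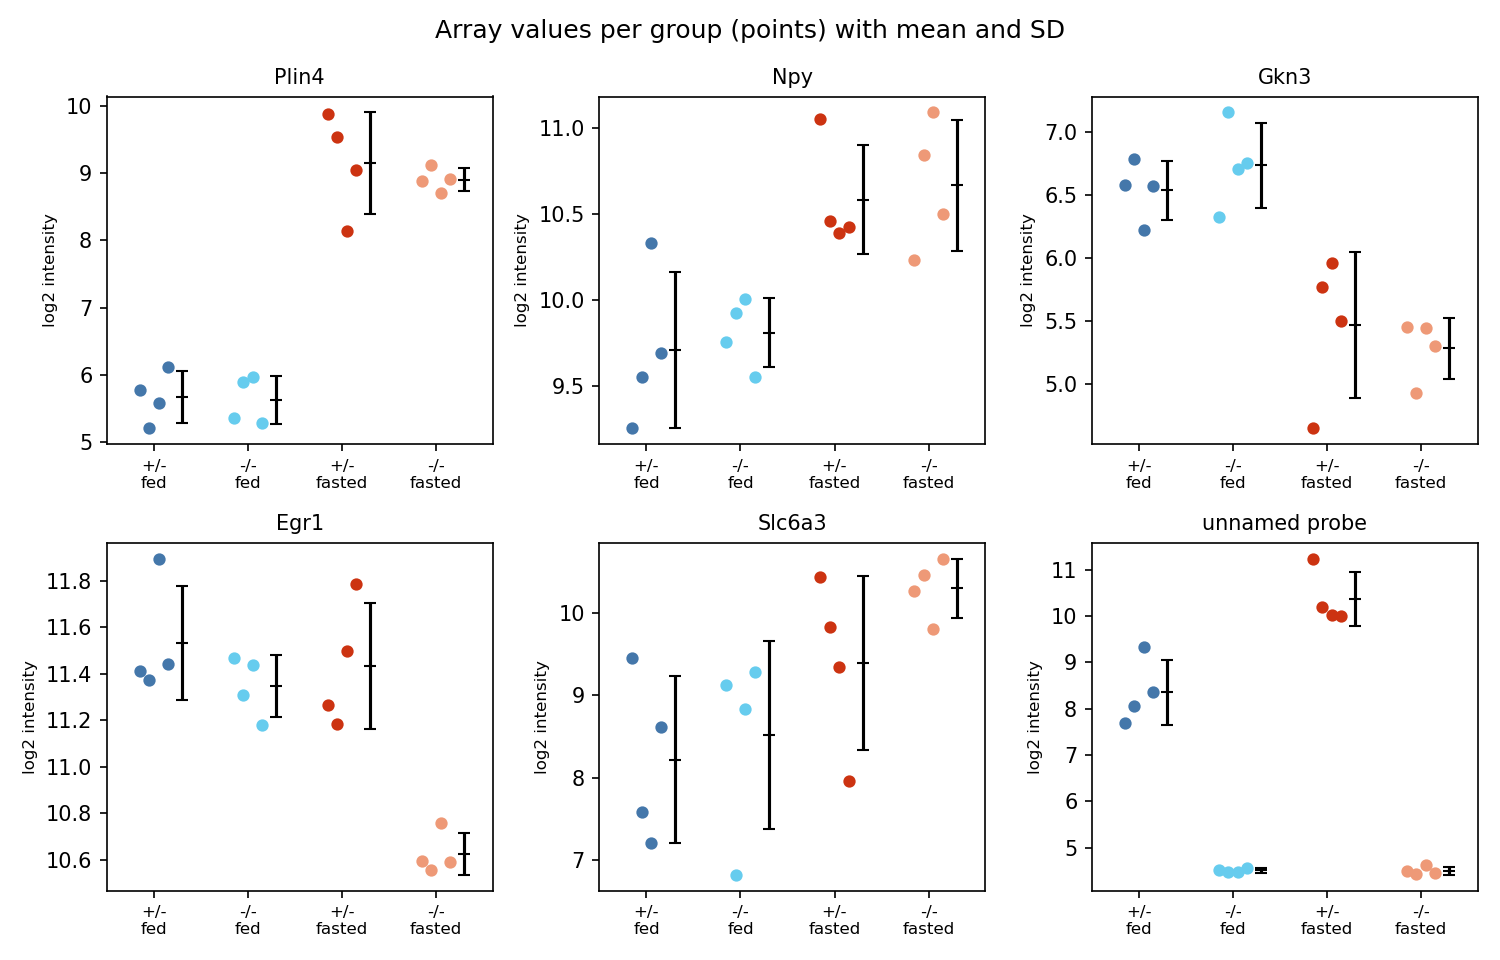
Log2 intensity (y axis) of Plin4, Npy, Gkn3, Egr1, Slc6a3 and the probe without a symbol in the 4 groups (x axis), with 1 point per array and the group mean with its SD. Plin4 rose by 3.38 and Gkn3 decreased by 1.26 with fasting averaged over genotypes, and the probe without a symbol lies between 4.43 and 4.62 on all 8 AgRP-/- arrays.

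**Figure D3:**
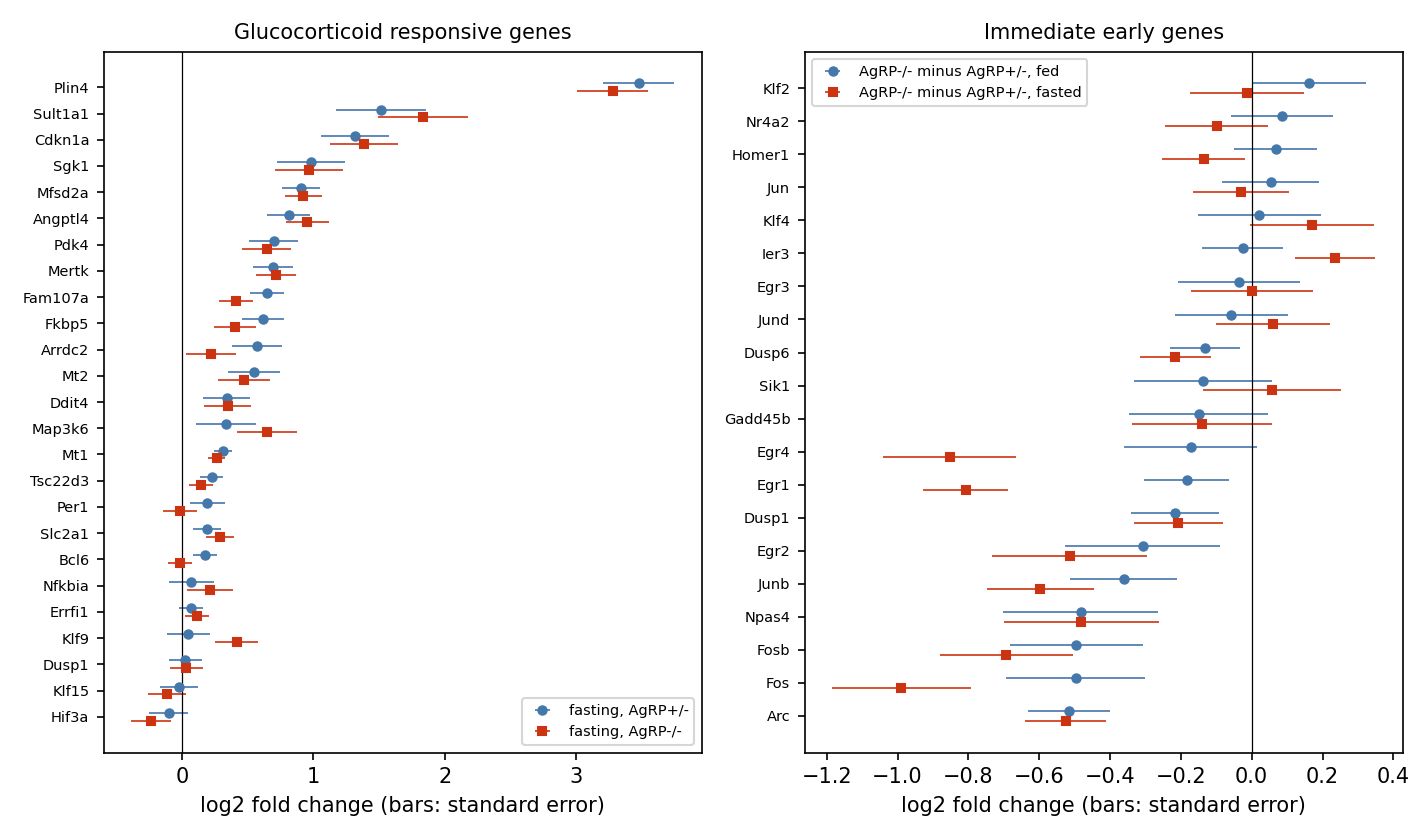
Log2 fold change (x axis) with its SE for each kept gene (y axis) of the glucocorticoid responsive list with fasting in each genotype (left) and of the immediate early list for AgRP-/- minus AgRP+/- in fed and fasted mice (right). List medians were 0.34 and 0.40 on the left and -0.14 and -0.17 on the right.

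Few transcripts passed the test between the genotypes. In fasted mice Egr1 was lower in AgRP-/- than in AgRP+/- mice, at -0.81 (SE 0.12, limma adjusted p = 0.0121), with all 4 AgRP-/- arrays below the 4 AgRP+/- arrays. Averaged over feeding states Arc, an activity-regulated gene of dendrites (-0.52, adjusted p = 0.021), and Egr1 (-0.50, adjusted p = 0.0395) were lower, and Gfap, the intermediate filament gene of astrocytes, was higher (0.68, adjusted p = 0.021). Npy, Pomc and Cartpt were not called in any genotype contrast, with averaged differences of 0.092, 0.15 and -0.0041. Across kept probes, which are not independent replicates, the genotype differences in fed and fasted mice had a Pearson correlation of 0.285 and a Spearman correlation of 0.231. The jackknife SE of the former was 0.183, so it was not clearly above 0, and it was 0.154 without AgRP-/- fed replicate 3, 0.177 with array weights, 0.452 with the stricter filter and 0.429 with the Actb difference as covariate.

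In fed mice 1 probe was called with limma, the one without a symbol (2 without AgRP-/- fed replicate 1), and 584 had an unadjusted p under 0.05, where 683 would be expected by chance. In fasted mice 2 were called, that probe and Egr1, with 939 at an unadjusted p under 0.05, and the averaged contrast called 4, that probe, Arc, Egr1 and Gfap. The 20 kept immediate early genes had a median of -0.14 in fed mice (camera adjusted p = 0.00255; adjusted p = 0.393 with an estimated correlation), with 0 called and 1 lower when adjusted over the list alone. In the same contrast markers of neurons had a median of -0.10 (9 of 11 below 0, camera adjusted p = 0.166; unadjusted p = 0.0268). Those of striatum and thalamus had medians of -0.10 (7 of 7 below 0, camera adjusted p = 0.127; unadjusted p = 0.0182) and -0.13 (8 of 9 below 0, camera adjusted p = 0.232; unadjusted p = 0.0422), and those of cortex and hippocampus 0.020. In fasted mice the median of the immediate early genes was -0.17 (camera adjusted p = 9.29e-06; adjusted p = 0.18 with an estimated correlation), with 1 called and 6 lower when adjusted over the list alone. Averaged over feeding states it was -0.16 (camera adjusted p = 2.52e-06; adjusted p = 0.151 with an estimated correlation), with 2 called and 8 lower when adjusted over the list alone. Fos read -0.74 (adjusted p = 0.06) and Fosb -0.59 (adjusted p = 0.229) in the averaged contrast. Markers of mural and meningeal cells had a median of 0.61 over 12 genes in fasted mice (camera adjusted p = 0.00255; adjusted p = 0.715 with an estimated correlation) and of 0.45 averaged (camera adjusted p = 0.0147; adjusted p = 0.83 with an estimated correlation), with 0 called and 0 when adjusted over the list alone. In fasted mice Igf2 read 1.28, Lum 0.85, Vtn 0.68 and Acta2 0.55. Among 12 astrocyte markers Gfap was called in the averaged contrast, while Sox9 read 0.14 and Aqp4 0.11.

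In fasted mice Egr1 lost its call without AgRP-/- fasted replicate 1, 2 or 4 (adjusted p = 0.0732, 0.0783 and 0.068), without the intensity trend (0.132) and with the dopamine transcripts as a covariate, at -0.68 (SE 0.12, adjusted p = 0.0931). The averaged count was 1 with the Actb difference as covariate, where the calls were lost for Arc (-0.51, SE 0.091, adjusted p = 0.11), Egr1 (-0.50, SE 0.095, adjusted p = 0.14) and Gfap (0.61, SE 0.11, adjusted p = 0.14), and 2 with the dopamine transcripts, where they were lost for Arc (-0.50, SE 0.091, adjusted p = 0.138) and Egr1 (-0.41, SE 0.081, adjusted p = 0.259). It was 3 without the trend and 3 with array weights, where Egr1 lost its call (adjusted p = 0.173 and 0.0561), and Gfap lost its call at 0.69 without the 2 arrays with pituitary transcripts (adjusted p = 0.0528). It was 1 without the filter, with the stricter filter, and without AgRP+/- fed replicate 1 or AgRP-/- fed replicate 2, where Arc, Egr1 and Gfap all lost their calls (adjusted p = 0.0569 for each without the former, and 0.0597, 0.108 and 0.0831 without the latter). It was 2 without AgRP+/- fed replicate 4, AgRP-/- fed replicate 3 or AgRP-/- fasted replicate 1 or 2, where Arc (adjusted p = 0.0583, 0.0518, 0.0634 and 0.0631) and Egr1 (0.07, 0.0518, 0.125 and 0.128) lost their calls. It was 7 without AgRP-/- fed replicate 1 or AgRP+/- fasted replicate 2, while Egr1 also lost its call without AgRP-/- fed replicate 4, AgRP+/- fasted replicate 3 or AgRP-/- fasted replicate 4 (0.0992, 0.0706 and 0.0909) and Gfap without AgRP-/- fed replicate 4 (0.0616). Over all left-out arrays the differences ranged over -0.55 to -0.48 for Arc, -0.54 to -0.44 for Egr1 and 0.60 to 0.73 for Gfap.

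Genes that neighbour Agrp were examined because a targeted allele can carry flanking sequence of another strain. Of 52 kept neighbours, from a fixed list written from memory, 0 were called in any genotype contrast with limma. At an unadjusted p under 0.05, 9 of 52 (17.3%) passed in fasted mice against 7.08% of other genes (Fisher's exact test, two-sided, p = 0.0105, adjusted p = 0.063 over 12 such tests of genes near Agrp). By the same Fisher's exact test, in fed mice 2 of 52 (3.85%) passed against 4.29% (p = 1), and averaged 7 of 52 (13.5%) against 8.9% (p = 0.225, adjusted p = 0.45). Windows of 5, 10 and 20 megabases on either side of Agrp also held 0 called genes. In fasted mice 12 of 75, 13 of 111 and 25 of 233 of their genes passed (16%, 11.7% and 10.7%, against 7.05% to 7.08% of other genes). Fisher's exact p was 0.0102, 0.0641 and 0.0383 (adjusted p = 0.063, 0.192 and 0.153). In fed mice and averaged it was 0.217 or more.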

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

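The tests of dopamine transcripts varying together and of their covariate, and both tests of immediate early genes, were chosen after the result was seen, and so was the use of an upper bound for the correlation with the Actb difference and of a jackknife error for the immediate early genes, without which these tests would have counted against RNA quality.

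In 592 groups of 4 arrays, from 148 genes, 33 held an array whose gap to its nearest neighbour exceeded Dixon's 95% critical value as a share of the group's range, where chance gives about 1 in 20 groups, or 30. For each gene the array's side of the group and its gap as a share of the range follow. In AgRP+/- fed mice these were replicate 1 for Cd14 (below, 0.958), Pglyrp1 (below, 0.87) and Tst (above, 0.871), replicate 2 for Thra (above, 0.898), replicate 3 for Cdkn1a (above, 0.868), Egr1 (above, 0.864), Mobp (below, 0.859), Pomc (above, 0.85) and Sostdc1 (above, 0.977), and replicate 4 for Pdk4 (below, 0.849). In AgRP+/- fasted mice these were replicate 1 for Gad1 (above, 0.914), Npy (above, 0.894) and the probe without a symbol (above, 0.842), replicate 2 for Clic6 (above, 0.902), replicate 3 for Hsph1 (above, 0.918), and replicate 4 for Gfap (above, 0.841). In AgRP-/- fed mice these were replicate 1 for Enpp6 (below, 0.871) and Serpina3n (below, 0.85), replicate 2 for Acadl (above, 0.891) and Rpl3l (above, 0.926), replicate 3 for Acta2 (above, 0.9), Fgfr3 (below, 0.939), Lum (above, 0.903) and Npy2r (above, 0.899), and replicate 4 for Sel1l (above, 0.921). In AgRP-/- fasted mice these were replicate 1 for Oxt (below, 0.921), replicate 2 for Homer1 (above, 0.938) and Scd1 (above, 0.847), replicate 3 for Elovl5 (below, 0.853), Mobp (below, 0.925) and Nsdhl (below, 0.977), and replicate 4 for Rpl23a (below, 0.837) and Sesn1 (below, 0.846).

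Of 12 kept transcripts of midbrain dopamine neurons 5 were called higher after fasting, and 7 were not called (adjusted p from 0.0597 to 0.56). Deviations of the called transcripts from the group means correlated across arrays with a median of 0.668 over 10 pairs (range 0.0212 to 0.897). The 5 kept midbrain transcription factors had a median change of 0.247 (camera p = 0.0328, unadjusted and at the preset correlation). Their changes ran from -0.10 for Barhl1 to 0.67 for En2, with 4 above 0 and 0 called. An estimated correlation was not used for them. More midbrain tissue in the fasted samples would give both patterns. With the mean of Slc6a3, Chrna6 and Th as a covariate 60 of 62 other named genes (96.77%) held at least 50% of their change, with a median share of 93.6%. Calls were left for 9 of them, among them Plin4 at 3.15 (SE 0.28, adjusted p = 1.9e-05). SEs over kept probes grew 1.5-fold in the median while some changes shrank, as for Sult1a1, from 1.68 (SE 0.24) to 1.22 (SE 0.34, adjusted p = 0.132), and Egr1, from -0.41 (SE 0.085) to -0.20 (SE 0.11, adjusted p = 0.465). The slope of the covariate rests on deviations within groups, where error in its transcripts weakens the adjustment. The share held therefore cannot decide whether midbrain tissue was the whole cause of the fasting calls. A response of dopamine neurons to fasting stays open and was not tested.

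The Actb probes differed in their fasting change. With the Actb difference as a covariate 60 of 64 named genes (93.75%) held at least 50% of their change, with a median share of 106%. Calls were left for 23 of them. SEs over kept probes grew 1.33-fold in the median, as for Egr1, from -0.41 (SE 0.085) to -0.41 (SE 0.12, adjusted p = 0.0816). Some changes also shrank, as for Fos, from -0.61 to -0.29 (adjusted p = 0.39), and Acat1, from 0.46 to 0.23 (adjusted p = 0.518). The Actb difference was not shown to track RNA quality, so these values cannot decide whether RNA quality was the whole cause of the fasting calls. Probe differences of 2449 other genes followed the Actb difference within groups with a correlation of 0.125 (permutation p = 0.687, upper 95% bound 0.632), so a difference in RNA quality between the arrays cannot be told apart from a change in Actb transcripts because that bound leaves a strong relation open. No biological explanation was tested.

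Immediate early genes had a list median of -0.159 for AgRP-/- minus AgRP+/- mice averaged over feeding states, with 2 of 20 called lower (camera adjusted p = 2.52e-06; adjusted p = 0.151 with an estimated correlation). A single array did not account for it, since leaving out each of the 16 arrays gave medians from -0.216 to -0.122. With the Actb difference as a covariate the median was -0.104, and with a jackknife error of 0.0838 a part played by RNA quality cannot be told apart from an effect of genotype. The genotype itself stays open as an untested explanation.

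Splits of the arrays into other groups of the same sizes were counted for each contrast. For fasting in AgRP+/- mice 1 of 35 splits, the real one, called 103 probes and the highest other called 4. No smaller share is possible with 35 splits, so this argues against chance without excluding it. For fasting in AgRP-/- mice the count of splits alone does not exclude chance, since 2 of 35 splits called as many as the real 53, with 95 in the highest other. In the separate AgRP+/- arrays 53 of the 53 had the same sign, and 28 were called higher and 5 lower in both genotypes where independent lists would share 0.211 and 0.0293. Probes vary together and all groups share a single spread per probe, so those expected numbers do not measure chance. The agreement argues against chance only to that extent, and more midbrain tissue in all fasted samples would give it too. For genotype in fed mice 2 of 35 splits tied (real 1, highest other 1), so the count does not exclude chance either, but the called probe, ILMN_2703427, was called again in the separate fasted arrays (adjusted p = 1.49e-07 and 7.14e-11). In fasted mice the count does not exclude chance (real 2, highest other 2, 2 of 35 splits), which for Egr1 stays open. For fasting averaged over genotypes 1 of 100 drawn splits, the real one, called 572 and the highest other 30, which argues against chance without excluding it. For genotype averaged over feeding states 1 of 100 drawn splits, the real one, called as many as 4, with 2 in the highest other. The 4 include ILMN_2703427, which was also called in each feeding state, so the count does not exclude chance for Arc, Egr1 and Gfap. The interaction called 0 probes, a count that all 100 of 100 drawn splits must reach (highest other 101), so the splits say nothing about it, and a split that reverses feeding in a single genotype turns the fasting response into an interaction. For these last 3 contrasts the splits were drawn anew after the counts of another draw, which could repeat splits, had been seen. The highest other split of that draw was higher in each of the 3, stayed below the real count for fasting averaged over genotypes, and exceeded it in a single split for genotype averaged over feeding states. The share of splits argued against chance in both draws for fasting averaged over genotypes, but the highest other counts are not stable values.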

How the results depend on the processing

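Both covariates and the fit without 2 arrays were chosen after seeing the data, and the causes of the shifts below were not tested unless stated. Repeated quantile normalization and median centring left every count of called probes within 1.5 times of its reported value. For fasting in AgRP+/- the 103 called probes became 30 with only the groups compared, where fewer arrays enter, 63 with the Actb difference as covariate, 19 with dopamine transcripts as covariate, and 45 without the 2 arrays with pituitary transcripts. For fasting in AgRP-/- the 53 became 29 with no variance trend, 143 with array weights, 87 with only the groups compared, 83 with the Actb difference and 1 with dopamine transcripts. For fasting averaged over genotypes the 572 became 176 with the Actb difference and 33 with dopamine transcripts. For genotype in fed mice the 1 became 0 with 1 probe per gene, which leaves out the probe without a symbol. For genotype in fasted mice the 2 became 1 with no variance trend, 1 with 1 probe per gene and 1 with dopamine transcripts. For genotype averaged over feeding states the 4 became 1 with no filter, 1 with the stricter filter, 1 with the Actb difference, 2 with dopamine transcripts and 7 without the 2 arrays. The agreement of the fasting response between the genotypes rose from 0.498 to 0.651 with the Actb difference, the genes near Agrp at an unadjusted p under 0.05 in the averaged genotype contrast went from 7 to 4 with the stricter filter, which tests fewer genes, and the 19 gene list shifts became 0 with an estimated correlation. Leaving out 1 array at a time gave 41 to 107 probes for fasting in AgRP+/-, 27 to 42 for fasting in AgRP-/-, 1 to 2 for genotype in fed mice, 1 to 3 for genotype in fasted mice, 0 to 1 for the fasting by genotype interaction, 301 to 560 for fasting averaged over genotypes and 1 to 7 for genotype averaged over feeding states. It gave 0.418 to 0.528 for the agreement of the fasting response, 0.154 to 0.351 for the agreement of the genotype difference between feeding states, 5 to 10 genes near Agrp and 13 to 30 gene list shifts. Whether the replicate numbers pair the arrays stays open. Deviations of same-numbered arrays correlated from -0.187 to 0.299 over 24 pairs (median 0.0216, against -0.0194 for other numbers), and 5 of 16 arrays correlated best with their own number. With the replicate block fasting called 113 probes in AgRP+/-, 90 in AgRP-/- and 630 averaged, against 103, 53 and 572. Counts other than that of fasting in AgRP-/- stayed within 1.5 times. Among called probes singled out by name or by genotype difference, those that held their call whichever array was left out were 9 of 25 for fasting in AgRP+/-, 11 of 21 for fasting in AgRP-/-, 40 of 64 for fasting averaged over genotypes, 1 of 2 for genotype in fasted mice and 1 of 4 for genotype averaged over feeding states, and under the other alternatives chosen with the contrasts they were 9 of 25 for fasting in AgRP+/-, 12 of 21 for fasting in AgRP-/-, 41 of 64 for fasting averaged over genotypes, 1 of 2 for genotype in fasted mice and 1 of 4 for genotype averaged over feeding states, with 0 changing sign in either. Some other values, and Slc6a3, changed sign. Pomc for fasting in AgRP+/- was 0.058 with array weights and ranged from -0.23 to 0.20 with an array left out, Gad1 for fasting in AgRP+/- was 0.047 with the Actb difference, and Icam1 for fasting in AgRP-/- was -0.032 with dopamine transcripts. Pomc for genotype in fasted mice was -0.0026 with the Actb difference and ranged from -0.060 to 0.26, and Npy ranged from -0.048 to 0.31 for genotype in fed mice and from -0.059 to 0.24 for genotype in fasted mice. For the fasting by genotype interaction Npy was 0.026 with dopamine transcripts and 0.015 without the 2 arrays and ranged from -0.23 to 0.14, and Pomc ranged from -0.38 to 0.053. For fasting averaged over genotypes Slc6a3, itself part of that covariate, was -0.23 and Cspg4 -0.014 with dopamine transcripts, Olig1 was 0.0067 with the Actb difference, Cartpt was -0.063, -0.033 and -0.0054 with the Actb difference, with dopamine transcripts and without the 2 arrays and ranged from -0.029 to 0.078, and Pomc ranged from -0.20 to 0.016. Cartpt for genotype averaged over feeding states was 0.017 without the 2 arrays and ranged from -0.059 to 0.033, and the unnamed probe for fasting in AgRP-/- ranged from -0.046 to 0.016. The slide as a block was not run, since no slide was given in the sources used here, and alternatives for the level of Agrp were not run, since no probe was named Agrp. Signal over background limits dim probes, for which no detection values were used here.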

Other observations

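The midbrain transcription factors were listed after the called genes but before their own values were seen, and the dopamine neuron transcripts after their values were seen. Further gene groups held members called for fasting averaged over genotypes, although none of these lists passed camera. Among 22 autophagy and lysosome genes Lamp1, a lysosomal membrane protein, rose by 0.16 and the protease gene Ctsb decreased by 0.21 (limma adjusted p = 0.0434 and 0.0416; camera adjusted p = 0.971), and 2 were higher and 1 lower when adjusted over the list alone. Among 17 endoplasmic reticulum chaperones and genes of the unfolded protein response Ddit3 rose by 0.43 and Dnajb9 decreased by 0.29 (2 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.879), and among 20 genes of the amino acid response Psat1 rose by 0.40 and Atf5 decreased by 0.27 (5 and 1 when adjusted over the list alone; camera adjusted p = 0.463). Hspa8 decreased by 0.15 among 18 heat shock genes (1 higher and 3 lower when adjusted over the list alone) and Elovl5, a fatty acid elongase, decreased by 0.25 among 17 genes of fatty acid synthesis (2 and 5; camera adjusted p = 0.507 and 0.547). Lamp1, Ctsb, Ddit3, Dnajb9, Psat1, Atf5, Hspa8 and Elovl5 lost their calls with the dopamine transcripts as a covariate (limma adjusted p from 0.0778 to 0.47). With the Actb difference Psat1 kept its call (adjusted p = 0.00129) and the others lost theirs (adjusted p from 0.147 to 0.528). Mean and median differed in sign for the reticulum and microglia lists, and for the autophagy list both lay below 0 while camera pointed up.

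Among cell type markers in the same contrast, Cx3cr1, the fractalkine receptor of microglia, rose by 0.47 and Laptm5 decreased by 0.21 among 11 microglial markers (1 and 1 when adjusted over the list alone; camera adjusted p = 0.866). Clic6 and Sostdc1 decreased by 0.29 and decreased by 0.45 among 7 choroid plexus markers (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.469), and Lhx8 and Dlx1 decreased by 0.75 and decreased by 0.27 among 9 markers of hypothalamic nuclei (1 and 3 when adjusted over the list alone; camera adjusted p = 0.48). Enpp6 rose by 0.41 among 8 markers of oligodendrocyte precursors (1 higher when adjusted over the list alone; camera adjusted p = 0.544). With the dopamine transcripts as a covariate Clic6, Sostdc1, Dlx1 and Enpp6 lost their calls at -0.15, -0.28, -0.14 and 0.21 (limma adjusted p = 0.609, 0.497, 0.597 and 0.616). Lhx8 lost its call there at -0.68 (limma adjusted p = 0.187), as did Cx3cr1 at 0.48 and Laptm5 at -0.245 (limma adjusted p = 0.332 and 0.148). With the Actb difference Cx3cr1, Laptm5, Clic6, Sostdc1, Dlx1 and Enpp6 lost their calls (adjusted p from 0.0506 to 0.145), while Lhx8 kept its call (adjusted p = 0.0409). Of 5 kept midbrain transcription factors 0 were called higher and 0 lower with limma, with changes from -0.10 for Barhl1 to 0.67 for En2 and a median of 0.25 (adjusted p from 0.0709 to 0.846). Irx5, Irx3 and Irx2 read 0.043, 0.25 and 0.43. The 7 transcripts of dopamine neurons that were not called were Drd2 (0.18), Gch1 (0.19), Slc10a4 (0.26), Ddc (0.26), Ret (0.39), Aldh1a1 (0.39) and Slc18a2 (0.44).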
